A study of Mus musculus with 6 samples.

How the data were processed

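The series holds 6 RNA-seq libraries of mouse intestine, 3 labelled wild type (WT) and 3 labelled knockout (KO). Per the labels, RNA was extracted with TRIzol, polyadenylated RNA was selected, and libraries were made with a stranded kit for low RNA input. The design text of the series speaks of the whole duodenum, the first part of the small intestine, and the cell type label lists epithelium, immune cells and enteric neurons. Which gene was knocked out, whether the libraries came from separate animals, and the sex and age of the mice are not given in the sources used here. All p-values measure the spread between these libraries, which may in part be technical.

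The authors deposited 1 table of log values for the whole series, taken here as log2(abundance + 1). The genome build is mm10, per the labels. The aligner, the counting tool and its strand setting, the abundance unit, the log base and the added constant are not given in the sources used here. Base 2 is an assumption: it gives linear sums between 277207 and 314569 per library and a factor of 2.12 for KO 1, where 2.23 is predicted from the part of the signal that KO 1 covers. Base e gives sums between 2698995 and 3086926 and a factor of 2.89, where 2.65 is predicted, so these values do not settle the base. Under base e, every log2 fold would be larger by one constant factor, and the rescaled values of KO 1 would differ. A fold on this scale understates the change of genes near 0. The values show no steps of whole reads, so the depth of each library is unknown and no counting interval can be given. Without a stated strand setting, a gene cannot be separated from a gene on the opposite strand that overlaps its exons.

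Of 32245 rows, 26 had a date in place of a gene symbol and were left out, which left 32219 genes. Every column matched the title of 1 sample. GENCODE vM21, which uses the same mouse assembly as mm10 (GRCm38), placed 31398 symbols on a chromosome, and 821 were not placed. Genes above 0 in at least 3 of the 6 libraries were kept, which gave 22178.

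KO was compared with WT by limma 3.58.1 in R 4.3.3, with a variance trend, 2-sided, with group as the sole term. Benjamini-Hochberg adjustment ran over the 22178 genes and the threshold was an adjusted p under 0.05. For gene lists, camera with a preset correlation of 0.01 was run over 52 lists written beforehand, of which 51 had at least 5 genes kept, with adjustment over the lists. These choices, the lists and the rule for named genes were fixed before the data were examined. The rule named Dhx9 and Ffar3, the genes of the series title. It also named, in each direction, the 12 genes past the threshold with the largest folds whose groups did not overlap and whose mean was at or above the median of the genes kept. Where none passed in a direction, the 5 with the smallest p were named as not passing. Predicted genes (Gm, Rik) and immunoglobulin or T cell receptor segments were left out. Of each list described, up to 4 members with the smallest p could be named.

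The library KO 1 holds values for only part of the genome. The planned fit without KO 1 is therefore reported beside the fit of all 6 libraries. The naming rule was also applied to that fit, a choice made after the gap in KO 1 was seen. Gm49380, Gm44924, Zfp708 and Pycr1, and the marker genes given as values per library, were chosen after their values were seen. For the genes that KO 1 covers, its linear values were divided by 2.12, the median ratio to the mean of the other libraries over 2159 genes at 4 or more on the log2 scale. These rescaled values are named as such wherever they appear.

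Other settings chosen beforehand were the replicate number as a block, median centring, quantile normalization, no filter, a stricter filter, added constants of 0.1 and 5, other variance models, other thresholds, leaving out each library, camera with an estimated correlation, and fry. Added after the data were seen were fits with KO 1 rescaled, and each of the same settings, and a covariate for the Xist level, on the 5 libraries without KO 1. Count models were not run, since the table holds no counts.

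The test was tried on simulated values with the means and spreads of the real genes, in 5 runs with 200 changed genes each. The changed genes were the same in every run and were drawn from genes at or above the median WT mean. Counts out of 500 therefore repeat the same genes over the runs. The recoveries hold for that upper part, and changes in lower genes were not simulated. With 3 WT against 3 KO libraries, limma recovered 78.6% of genes changed 2-fold and 92% of those changed 4-fold over 22177 genes. With 3 WT against 2 KO, it recovered 59.4% and 85% over 22174 genes, with a mean of 8 false calls per run. KO 1 was then set to 0 where the real library has no values, and its other linear values were multiplied by 2. With this KO 1, limma recovered 0 of the 500 genes of either size. A shift of 0.5 given to the 32 proliferation genes was found by camera in 5 of 5 runs without KO 1, and in 3 of 5 with an estimated correlation. The simulated genes vary independently, which real genes do not.

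Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.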

Results

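Whole-tissue RNA was profiled in 3 WT and 3 KO libraries of mouse intestine. The 5 libraries other than KO 1 listed between 22061 and 22768 of 32219 genes above 0, and KO 1 listed 9729. In KO 1, every gene above 1 on average in the other libraries was listed at 0 on chromosomes 2 to 9, X and M, where the other 5 libraries had at most 2.41% of such genes at 0. On chromosome 19, KO 1 had values up to Tmem258 (19, 10204014 to 10207824), which stood at 2.28 against 6.06 to 6.18 elsewhere, and the next gene, Myrf, was listed at 0, as were all 296 genes above 1 that follow Tmem258 on that chromosome. On chromosomes 1 and 10 to 18, KO 1 had from 0% to 1.89% of genes at 0. Housekeeping genes such as Gapdh (5.55 to 5.91 elsewhere) and Actb (10.13 to 10.42 elsewhere) were among those listed at 0, so a 0 in KO 1 says nothing about expression outside this range. Depth is unknown for all 6 libraries.

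**Figure D1:**
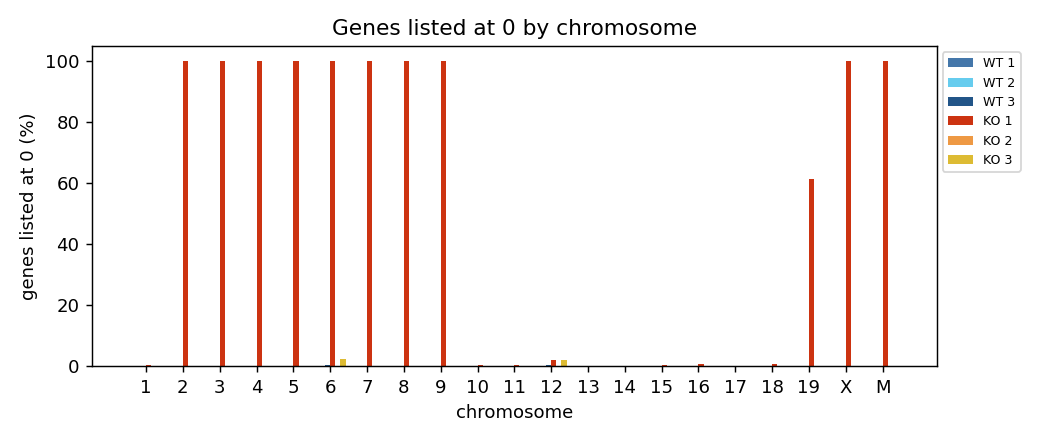
Percent of genes listed at 0 in each library (bars) by chromosome, among genes above 1 on average in the 5 libraries other than KO 1. KO 1 stands at 100% on chromosomes 2 to 9, X and M and at 61.2% on chromosome 19, while the other libraries stay at or below 2.41%.

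The genes of the series title were examined first, since the labels do not name the knocked-out gene. Dhx9, an RNA and DNA helicase (chromosome 1, 153455758 to 153487660, minus strand, protein-coding), was present in every library. Its log2 values were 5.94, 6.01 and 5.97 in WT, 6.17 in KO 2 and 6.08 in KO 3, and 7.10 in KO 1 as deposited or 6.03 rescaled. Ffar3, which encodes the short-chain fatty acid receptor GPR41 (chromosome 7, 30854330 to 30856178, minus strand), was low throughout, at 0.60, 0.18 and 0.46 in WT, 0.35 in KO 2 and 0.59 in KO 3. It was listed at 0 in KO 1, which has no values on that chromosome. Neither gene was lost in KO 2 or KO 3 at the level of the whole tissue. Such values cannot show a loss limited to some cell types or to part of a transcript. For Ffar3, low in WT as well, a loss would be hard to see. With all 6 libraries, limma gave Dhx9 a log2 fold of 0.48 ± 0.44 (SE, adjusted p = 0.718) and Ffar3 one of -0.10 ± 0.18 (adjusted p = 0.760). Without KO 1, the folds were 0.15 ± 0.08 for Dhx9 and 0.06 ± 0.14 for Ffar3, so the sign for Ffar3 turns with KO 1.

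With all 6 libraries, limma called 0 of 22178 genes changed between KO and WT after Benjamini-Hochberg adjustment, with 242 at an unadjusted p under 0.05. The smallest adjusted p was 0.470, and 6.46% of genes had non-overlapping groups, against 10% by chance. The genes higher in KO with the smallest p, none past the threshold, were Ly6d, Rab26os, Atp5d, Tmem184b and Naa38, with log2 folds from 0.74 for Tmem184b to 1.18 for Ly6d. Those lower in KO were Sprr2b, Car1, Ifit3, Sval1 and Nr2f6, with folds from -1.42 for Sval1 to -3.54 for Sprr2b. All 5 of the higher genes lie where KO 1 has values and all 5 of the lower genes where it has none. KO 1 also lifted the covered genes by a factor of 2.12: the median log2 fold was 0.23 over 10070 covered genes and -0.67 over 11708 genes not covered. The simulation with this gap, and with the covered values of KO 1 raised, recovered 0 of 500 genes changed 4-fold, so this fit could call little.

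Without KO 1, 1 gene passed: Gm49380, at 0, 0.07 and 0 in WT and 1.78 and 1.82 in KO 2 and KO 3, with a log2 fold of 1.78 ± 0.09 (SE) and an adjusted p of 0.0189 by limma. This predicted gene (chromosome 9, 44066327 to 44113500, minus strand) shares exon sequence with Rnf26 and Usp2, so the assignment of reads among these genes is uncertain. Rnf26, a ubiquitin ligase, was at 3.99 ± 0.07 (SD, n = 3) in WT and 3.71 ± 0.01 (SD, n = 2) in KO. In this fit 494 genes had an unadjusted p under 0.05, fewer than the 1109 that chance gives, and 13.6% of genes had non-overlapping groups against 20% by chance. When any 1 of the remaining 5 libraries was left out, the fold of Gm49380 stayed at 1.76 to 1.80, but its adjusted p by limma was 0.0891 to 0.550; with the Xist level as a covariate it was 0.110.

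Other genes kept KO 2 and KO 3 apart from WT without passing. Ppp2r3d, a regulatory subunit gene of protein phosphatase 2A, stood at 3.17 ± 0.02 (SD, n = 3) in WT and at 4.83 and 4.37 in KO 2 and KO 3 (log2 fold 1.43 ± 0.15, limma adjusted p = 0.423). Pycr1, a proline synthesis enzyme, stood at 2.31 ± 0.05 in WT (SD, n = 3), at 1.04 and 0.99 in KO 2 and KO 3, and at 0.73 in KO 1 after rescaling. Zfp708, a zinc finger gene, was at 0.85, 1.15 and 1.10 in WT and listed at 0 in all 3 KO libraries, including KO 1, which covers its chromosome. Gm44924 was at 0.65, 0.59 and 0.68 in WT and listed at 0 in KO 2 and KO 3. Among genes that the rule named, Tmem184b (0.44), Cuedc2 (0.39), Atp5d (0.46), a subunit gene of ATP synthase, and Zfp408 (0.50) were higher in KO 2 and KO 3. Dnm1 (-0.67), Mrpl3 (-0.39), Sval1 (-0.68), Thoc7 (-0.31) and Rnf26 (-0.28) were lower, all as log2 folds with a limma adjusted p = 0.99998. Gm44924, Atp5d, Cuedc2, Mrpl3, Thoc7 and Rnf26 overlap exons of genes on the opposite strand.

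The fixed gene lists asked whether cell types and pathways moved together. Interferon-stimulated genes, the antiviral response set, fell by camera without KO 1 (37 of 37 members lower, median log2 fold -0.38, adjusted p = 4.25e-16; adjusted p = 0.975 with an estimated correlation). KO 3 was the lowest library: its median against the WT mean was -0.90, while KO 2 stood at 0.06, WT 1 at 0.41, WT 2 at -0.31 and WT 3 at -0.07. KO 1, over the 12 members that it covers and after rescaling, stood at 0.54, so among the KO libraries the fall rests on KO 3. Without KO 3 the list turned upward (adjusted p = 0.942), and over covered genes with KO 1 rescaled it had a camera adjusted p of 0.463. Ifit3 (log2 fold -0.77) and Rsad2 (-0.81), an antiviral enzyme, were among the members with the smallest p. Over all genes tested, 0 members passed by limma, and 0 passed adjusted over the list alone, with 1 at an unadjusted p under 0.05.

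Stromal lists fell by camera as well. The fibroblast and matrix list (25 of 26 members lower, median -0.18) had an adjusted p of 5.85e-08, the glia list (14 of 16, -0.10) 0.00620, the stem cell niche ligand list (19 of 30, -0.05) 0.00701 and the endothelial list (13 of 20, -0.06) 0.0433. Each of these had an adjusted p = 0.975 with an estimated correlation. Members with the smallest p were Mfap4 (-0.44) and Dpt (-0.34), both matrix proteins, S100b (-0.28) and Kcna1 (-0.29) of glia, Ereg (-0.39) and Nrg1 (-0.26), ligands of the epidermal growth factor receptor family, and Cldn5 (-0.45) and Egfl7 (-0.24) of endothelium. WT 2 stood apart, with a fibroblast median of 0.33 against its group's mean, while WT 1 was at -0.20 and WT 3 at -0.11, close to KO 2 at -0.19 and KO 3 at -0.15. Without WT 2 the fibroblast list had a camera adjusted p of 0.140, the glia list 0.186 and the niche list 0.247, and the endothelial list turned upward at 0.770. Without KO 2 the glia (0.405), niche (0.0888) and endothelial (0.4996) lists did not pass either. No member of these lists passed by limma over all genes, and 0 passed adjusted over the list alone.

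The unfolded protein response list fell (20 of 24 lower, median -0.08, camera adjusted p = 0.0181), with Creld2 at -0.31 and Hyou1, a chaperone of the endoplasmic reticulum, at -0.27, while Herpud1, the member with the smallest p, was at 0.20. Ribosomal protein genes rose (42 of 49 higher, median 0.08, camera adjusted p = 0.0211), with Rps20 at 0.31 and Rps10 at 0.21. So did the lipid absorption and PPAR alpha list (25 of 30, median 0.14, camera adjusted p = 0.0433), with Acadm, a fatty acid oxidation enzyme, at 0.25 and Apoa4 at 1.05. The Apoa4 fold rests on KO 3, at 5.49, while KO 2 stood at 3.54 against a WT mean of 3.46. All 3 lists had a camera adjusted p = 0.975 with an estimated correlation, and 0 members of each passed over all genes by limma or adjusted over the list alone. Mature enterocyte markers, which share Apoa4 with the lipid list, were higher alongside it without passing (27 of 33, median 0.16, camera adjusted p = 0.0511), with KO 2 at -0.07, KO 3 at 0.39 and KO 1, over its covered members after rescaling, at 1.07. Without KO 3, the lipid list turned downward (adjusted p = 0.697), and without WT 2 it did not pass (0.272). Also without KO 3, the unfolded protein response list no longer passed (0.355), nor did it without WT 3 (0.778). The ribosomal list no longer passed without WT 1 (0.717), WT 2 (0.247) or KO 2 (0.389). In all, 8 of 51 lists passed by camera without KO 1, 2 up and 6 down, with 14 at an unadjusted p under 0.05; camera with an estimated correlation and fry called 0. Each of the 9 other ways to split these 5 libraries called more lists, 11 to 28.

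**Figure D2:**
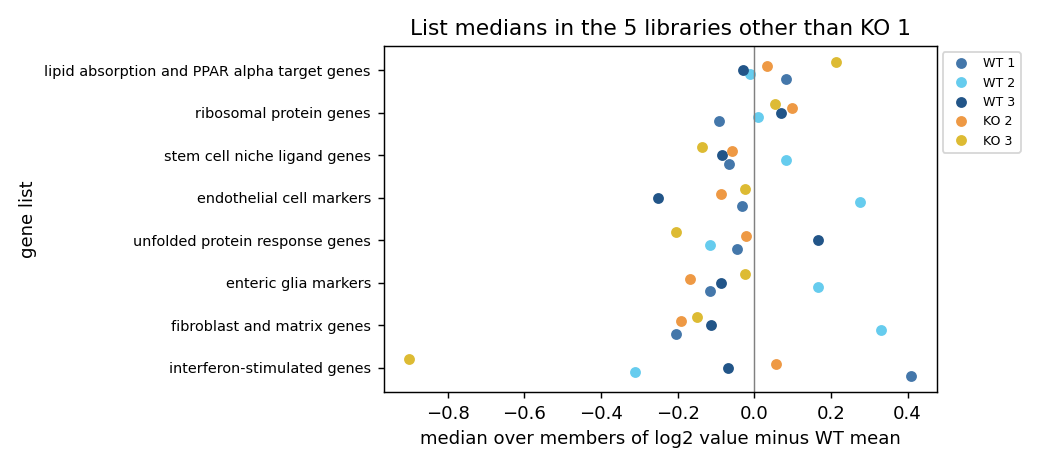
Median over list members of the log2 value minus the WT mean (horizontal axis) for each of the 8 lists past the camera threshold without KO 1 (vertical axis), 1 point per library. KO 3 stands at -0.90 for interferon-stimulated genes and WT 2 at 0.33 for fibroblast and matrix genes.

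Lists close to the series title did not pass without KO 1. Of 24 intestinal stem cell markers, 16 were higher and 8 lower (median 0.06, camera adjusted p = 0.651), with Lgr5, the marker of crypt base stem cells, at 3.71 ± 0.11 (SD, n = 3) in WT and 4.01 and 3.92 in KO 2 and KO 3, and Ephb3 at a log2 fold of 0.23. KO 1 was lower after rescaling, at 2.91 for Lgr5 and 2.42 for Ephb3. Its list median, over the 13 members that it covers, was -0.60 against the WT mean. With KO 1, the folds of Lgr5 and Ephb3 over covered genes were -0.09 and -0.08. Of 19 serotonin pathway genes, 8 were higher and 11 lower (median -0.01, adjusted p = 0.696), with Slc18a1, a vesicular monoamine transporter, at 0.31, the receptor gene Htr1d at 0.06 and Maoa at -0.21. Tph2, the neuronal enzyme of serotonin synthesis, was listed at 0 in all 6 libraries. Of 40 enteric neuron markers, 24 were higher and 16 lower (median 0.02, adjusted p = 0.569), with Nmu at -0.40 and Elavl3 at 0.22. Of 32 proliferation genes, 21 were higher and 11 lower (camera adjusted p = 0.753). The DNA damage and R-loop response list (17 of 23 higher, median 0.13) had a camera adjusted p of 0.144. The short-chain fatty acid receptor and transport list (10 of 15 higher, median 0.02) had a camera adjusted p of 0.946. In each of these lists, 1 or fewer members had an unadjusted p under 0.05 by limma and 0 passed over all genes or adjusted over the list alone.

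With all 6 libraries, 8 lists also passed by camera, 3 of them the same as without KO 1 (interferon-stimulated, fibroblast and glia). Histone genes rose (adjusted p = 0.00395) and antigen presentation genes rose (0.0316), while smooth muscle markers (0.00395), enteric neuron markers (0.00395) and mitochondrial DNA-encoded genes (0.00693) fell. All 8 had an adjusted p = 0.959 with an estimated correlation. Of the 20 histone genes kept, 18 lie where KO 1 has values, and of the 13 mitochondrial genes none do. Of the 37 interferon-stimulated genes kept, KO 1 covers 12, where it stood at 0.54 against the WT mean after rescaling. Its listed zeros elsewhere thus pull this list down in the fit of all 6 libraries. Without KO 1 the histone list turned downward (adjusted p = 0.569), and the smooth muscle (0.116), neuron (0.569), mitochondrial (0.506) and antigen presentation (0.913) lists no longer passed.

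Where KO 1 has values, it still stood apart after rescaling. It held 76 genes at least 2 log2 units outside the range of the other 5 libraries, while no other library held more than 2. Gata4, a transcription factor of the proximal small intestine, stood at 5.19 against 0.43 to 0.63 elsewhere, Lct, the lactase gene, at 7.05 against 1.08 to 2.01, and Gip, a hormone of K cells, at 4.02 against 0.27 to 1.22. Fabp6, the ileal bile acid binding protein, stood at 3.91 against 8.16 to 8.76, Hoxb9 at 0.16 against 4.10 to 4.29, and the smooth muscle genes Myh11 and Des at 3.80 and 2.25 against 7.34 to 7.82 and 6.82 to 7.37. The other 5 libraries all expressed the ileal bile acid genes Slc10a2 (5.98 to 6.76) and Fgf15 (5.02 to 5.84), on chromosomes for which KO 1 has no values. The design text names the duodenum, whereas these 5 libraries are high in distal genes and low in Gata4 and KO 1 is the reverse. These levels argue against the duodenum for the 5 libraries. Which gut segment the folds without KO 1 describe is therefore uncertain. Correlations across covered genes, which are not independent replicates, were computed with KO 1 as deposited, not rescaled. They were 0.896 to 0.924 between KO 1 and the other libraries and 0.968 to 0.986 among those.

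**Figure D3:**
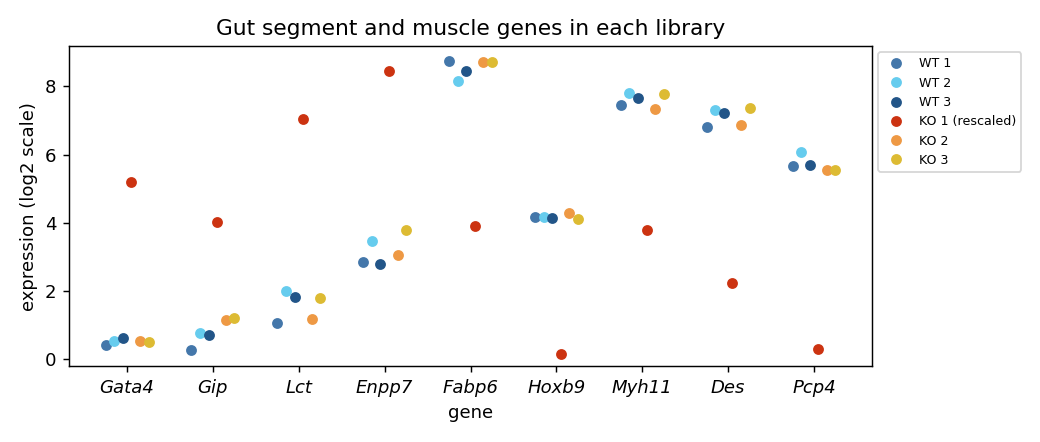
Log2 expression (vertical axis) of 9 genes (horizontal axis) in each library, 1 point per library, with KO 1 rescaled by its factor of 2.12. KO 1 is the highest library for Gata4, Gip, Lct and Enpp7 and the lowest for Fabp6, Hoxb9, Myh11, Des and Pcp4.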

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

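The fits of the 5 libraries without KO 1 under other settings were chosen after the data were seen. With all 6 libraries, limma called 0 genes under each planned setting except without KO 1, where it called 1, so the range over left-out libraries was 0 to 1; with KO 1 rescaled and missing where not covered it called 1. For the 1 gene called without KO 1, Gm49380 (fold 1.78), 0 genes passed with the replicate block (fold 1.76, adjusted p 0.0924), the Xist covariate (1.77, 0.110), an added constant of 0.1 (4.49, 0.0803), any further library left out (1.76 to 1.80, 0.0891 to 0.550), no filter, where more genes are tested, and the stricter filter, which leaves it out. Of 8 lists with 6 libraries, median centring gave 18 and quantile normalization 17, but only 4 of the 8 under each (neuron 0.286 and 0.103, glia 0.423 and 0.571, antigen presentation 0.172 and 0.377 and histone 0.579 and 0.398 did not pass), and the stricter filter gave 5 (neuron 0.0561, antigen presentation 0.0749), with 5 to 10 over left-out libraries, and camera with an estimated correlation and fry gave 0. Of 8 lists without KO 1, median centring gave 15 with all 8, and the Xist covariate 13 with 7 of the 8 (unfolded protein response 0.0609); the lipid list did not pass with no filter (0.0707) or a constant of 5 (0.0512), nor the endothelial list with no filter (0.0707) or the stricter filter (0.0617). Left-out libraries gave 7 to 20, where a lone KO library is assumed to vary like the others; an estimated correlation and fry gave 0. The replicate block called 0 genes and kept the 8 lists with 6 libraries, and gave 0 genes and 17 lists without KO 1, 7 of them among the 8, with the ribosomal list at an adjusted p of 0.871. Deviations of libraries with the same number correlated at 0.04, 0.06 and 0.12 as deposited, at 0.26, 0.53 and 0.06 over covered genes with KO 1 rescaled, and without KO 1 at 0.30 and 0.35 for numbers 2 and 3. As a hint from the data, WT 2 and KO 2 (0.986) and WT 3 and KO 3 (0.982) were each other's closest libraries, while WT 1 was closest to WT 3 (0.977). The gap in KO 1 enters the KO mean behind the deviations as deposited, so those values cannot test pairing. Without KO 1, number 1 cannot be examined, and the deviations of KO 2 and KO 3 mirror each other. Numbers 2 and 3 thus go with pairing, but pairing stays open. The Ffar3 fold of -0.10 turned to 0.53 with centring, 0.070 with quantile normalization, and 0.060 both without KO 1 and with KO 1 missing where not covered (-0.24 to 0.060 over left-out libraries); centring moves the median of all genes from -0.07 to 0.57, which brings the sign change. The histone list turned without KO 1 (adjusted p 1.61e-04 to 0.569 over left-out libraries). In the fit without KO 1, the interferon (2.40e-32 to 0.942) and lipid (2.21e-04 to 0.697) lists turned without KO 3, and the endothelial list (9.24e-06 to 0.770) without WT 2. Other causes were not tested. Depth is unknown, so what it limits cannot be stated.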

Other observations

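Some genes differed between single libraries more than between groups. Transcripts of plasma cells, which secrete antibody, varied within both groups: Igha stood at 8.45 in WT 1, 6.85 in WT 2, 5.41 in WT 3, 6.68 in KO 2, 3.30 in KO 3 and, rescaled, 4.28 in KO 1, and Jchain, which KO 1 does not cover, at 5.92, 4.33, 3.02, 4.43 and 1.29. Ighd, an antibody gene of another class, followed another order, at 0.67, 4.57, 0.43, 5.43, 2.67 and, rescaled, 0.47. WT 2 and KO 2 carried the Y-linked genes Ddx3y (3.98 and 3.91) and Uty (4.61 and 4.68) with Xist at 0.20 and 0.21, while WT 1, WT 3 and KO 3 had Xist between 6.85 and 7.25 and Uty at 0.00 to 0.01. Fat cell genes were highest in WT 3 and KO 3, with Adipoq at 2.97 and 2.75 against 1.03 to 1.95 in WT 1, WT 2 and KO 2. In KO 1, which covers Adipoq, it was listed at 0.

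The tests of the patterns below were chosen after the patterns were seen, except the splits of the 6 libraries. Of the 10 splits of the 6 libraries, all 10 gave at least the 0 genes of the real split, as any split must, and the highest other gave 1. For lists, 4 gave at least its 8 and the highest other gave 13. The gap in KO 1 enters every one of these splits, so they say little about grouping by genotype. Of the 10 splits of the 5 libraries, 3 gave at least 1 gene and the highest other, WT 2 and KO 2 against the rest, gave 10, which points to a structure of the samples, as these share the sex-linked genes above. All 10 gave at least the 8 lists of the real split, which called the fewest; the highest other, WT 3 and KO 3 against the rest, gave 28, and genes at an unadjusted p under 0.05 were also fewest in the real split (494, against 555 to 1934), which points to structure among these libraries other than KO against WT. With 10 splits no share under 0.05 can be reached.

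The zeros of KO 1 follow the order in which chromosome names sort as text (1, 10 to 19, 2 to 9). Past Fen1 on chromosome 19 in that order, 0.0131% of genes above 1 elsewhere were above 0 in KO 1, which is consistent with a file or alignment that ended early. Low depth is argued against, since before that position KO 1 had 0.491% of such genes at 0. The genotype is argued against as well, since KO 2 and KO 3 had at most 0.274% of the genes past the position at 0.

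KO 1 also differed in kind on the covered genes, and a candidate explanation is a piece of gut from another place than in the other 5 libraries, whose own levels go against the duodenum of the design text. The smooth muscle, interstitial cell, neuron, glia and fibroblast lists all lay low in KO 1, the highest of them at the 0.025th percentile of 10000 matched random lists, as less muscle wall in the piece would give. The random lists were matched by level alone, while members of a cell type list vary together. These percentiles and those below can thus overstate how rare a shift is, and no other library was ranked this way. The proximal intestine list lay at the 99.4th percentile (6 genes, 4 higher and 2 lower, 2 of them on other lists). The distal list lay at the 0.075th (11 genes, 5 on other lists). A more proximal segment would give both. The adipocyte and mesentery list (5 genes, all lower, median -1.95) lay at percentile 0. Mature enterocyte markers (10 genes, 9 higher and 1 lower, median 1.07) lay at percentile 100. An effect of the genotype alone is argued against by the smooth muscle medians of the other KO libraries over 23 genes. The farther from WT was -0.23, against -2.65 in KO 1 over the 9 of these genes that it covers. On the 50 covered genes that best part KO 2 and KO 3 from WT, KO 1 was nearer to the KO libraries for 48%, as a sample of WT genotype could give, but other splits gave 6 to 66%, so this test says little.

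The genes that part KO 2 and KO 3 from WT without KO 1 tended to lie near each other. Of the 50 with the smallest p, 14 had another within 1000000 bases, against a median of 3 in 10000 matched draws. Few draws held over 9, and 0.04% held 14 or more. Alleles linked on shared stretches of a chromosome could give such neighbours. Pairs included Zfp708 with Rslcan18 on chromosome 13, which share exon sequence, and Gm49380 with Gm48853 on chromosome 9. Noise in neighbouring low genes could give this in any split. Of the 10 splits, 3 held as many, the real one included. The other splits had a median of 9 and reached 17, so noise cannot be told apart here. No pattern here is offered as an effect of the knockout.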
